A study of Homo sapiens with 42 samples.

How the data were processed

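Expression was profiled on 42 Affymetrix arrays, each with 54675 probe sets, hybridised with biotin-labelled RNA from 6 human cancer cell lines. The deposited values were log2 expression summaries per probe set, made by the authors with RMA (robust multi-array average, a background correction, quantile normalization and median polish) per the submitters' processing notes. The RMA version and whether all 42 arrays were summarised together were not given in the sources used here. The log2 values ran from 1.75 to 14.4 with none missing, and the array medians lay between 4.65 and 4.80. The number of arrays limits the precision. The genome build was not given in the sources used here, and no coordinates are reported.

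Probe sets were named from the platform annotation, whose gene symbols were checked against a current gene table through the Entrez identifier. Of the 54675 probe sets, 41097 carried 1 gene symbol, 1801 carried several and 11777 carried none. The Entrez identifier of 41043 probe sets was found in the gene table, and 0 symbols needed updating. Probe sets with several symbols or none were named for no gene, so that genes known only through such probe sets, TP53 among them, were not analysed here. List members left out for want of a named probe set included the heat shock genes HSPA1A, HSPA1B and HSPA8. The repair genes BRCA2, RAD51, FANCD2 and FANCA and the TP53 targets BBC3 and BTG2 were also left out. Each of the 19775 named genes was represented by the probe set with the highest mean over the 42 arrays, and 11874 genes that reached 6 on the log2 scale in at least 3 arrays were kept. Of these, 7821 had several probe sets. Probe sets that reached 6 in at least 3 arrays were compared only for the genes named by the rule below. Those of CCDC85B, RRP12, TAGLN, MYBL1, PSMD12, SQSTM1, CFLAR, PSMD6, MT1G, HK2, POLR1B and MDM2 went in opposite directions in at least 1 comparison. The other genes were not checked in this way.

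Groups were taken from the labels. A549, HCT116 and MCF7 were described by the submitters as TP53 wild type. H1299, SW620 and SKBR3 were not, and were grouped as non-wild-type by that omission. Each combination of line, agent and time had 1 array, so the cell line served as the replicate, with 3 lines per status. The p-values therefore measure only the spread between these lines. For each line the log2 change was the value at 6, 12, 24 or 36 h minus the 0 h value of that line, averaged over the 4 times. The effect of PFTα was the value with ATO and PFTα minus that with ATO alone in the same line at the same time, which pairs the arrays by cell line. Tests, samples, gene lists and the rule for named genes were fixed before the data were examined.

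Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over the 11874 genes and a threshold of 0.05 on the adjusted p. Tests were made for the mean change of the 3 lines of each status, the difference between the statuses, the PFTα effect in the 3 wild-type lines, each time alone, and the change from 6 to 36 h. The number of genes at least 2-fold from 0 h was counted per array and compared between the statuses by a two-sided exact permutation test, whose smallest possible p is 0.1 for 3 lines against 3. The PFTα comparison of these counts used a two-sided exact sign-flip test, whose smallest possible p is 0.25. The 21 gene lists were tested with camera at the preset correlation of 0.01, with an adjustment over the lists, and again with an estimated correlation and with fry. camera compares a list with the other genes, and fry asks whether its genes move, on balance, one way. They were NRF2 targets, metallothioneins and zinc export, heat shock response, ATF4 integrated stress response, ER chaperones and ER-associated degradation, TP53 targets, proteasome subunits, autophagy, DNA replication and E2F targets, mitosis, homologous recombination and Fanconi repair, NF-kB and cytokine genes, immediate early genes, cholesterol synthesis, hypoxia and glycolysis, interferon-stimulated genes, aryl hydrocarbon receptor targets, BCL2 family and apoptosis regulators, canonical histone genes, ribosome biogenesis, and TGF-beta and YAP target genes. Marker lists of breast luminal, colon and lung epithelium, fibroblasts, leukocytes and endothelium served as checks of the lines.

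Genes were named by rule. In each comparison these were the up to 8 largest rises and falls among genes past the threshold that moved the same way in all lines. Where fewer passed, the names were filled up to 6 per direction with the largest changes of one sign in all lines, or, for the difference, without overlap between the statuses, and are said not to have passed. From each list that passed, or whose name fits the agent, up to 4 members with the largest change were added, and MDM2, CDKN1A, HMOX1 and CYP1A1 were always included (TP53 was in the rule and was not analysed here). The rule was extended to the 36 h response of the non-wild-type lines after its counts were seen, with the members of each list past the threshold.

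The procedure was tested on simulated data with 11874 genes and 20 simulations. For the response of the non-wild-type lines it recovered 59.3%, 91.9% and 97.7% of genes changed by 2-fold, 4-fold and 8-fold. For the difference between the statuses it recovered 26.6%, 76.0% and 91.8%, and for the PFTα effect 56.9%, 88.2% and 94.8%. The share of false calls was 4.66%, 4.92% and 2.59%, respectively. A list shifted by 1 on the log2 scale was found in 20 of 20 simulations, and simulated lists without a shift gave 0 calls. The simulated genes were independent, and their spread was equal in all lines and not tied to the size of the change. These shares and counts therefore need not hold for lists of correlated genes, or for genes whose lines differ more as they change more.

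Alternatives were the mean of all probe sets of a gene, another or no filter on low values, quantile normalization applied again, subtraction of array medians, a moderated test with trend and robust settings, early or late times only, omission of each line, other fold thresholds, a fit over all arrays with the line as a block, tissue as a block, 12 pairs of line and time for PFTα, and an unpaired PFTα fit. Use of the 6 h array as the reference and the omission of lines at single times were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.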

Results

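Gene expression was measured on 42 arrays in 6 established human cancer cell lines treated with arsenic trioxide (ATO), an arsenic compound used against acute promyelocytic leukaemia, at 5 µM. A549 (lung), HCT116 (colon) and MCF7 (breast) were described by the submitters as TP53 wild type. H1299 (lung), SW620 (colon) and SKBR3 (breast) are called non-wild-type here because the submitters named only the other lines as wild type. TP53 encodes a transcription factor that is activated by DNA damage and other stress. Each line was sampled at 0, 6, 12, 24 and 36 h of ATO, which gave 30 arrays. The wild-type lines were also sampled at 6, 12, 24 and 36 h of ATO with PFTα (pifithrin-α, an inhibitor of TP53), which gave 12 arrays. The dose of PFTα was not given in the sources used here, and no arm with PFTα alone was analysed here. Nor was any array without ATO at 6 to 36 h. A change from 0 h, called the ATO response below, may therefore reflect ATO or time in culture. The PFTα effect compares arrays of the same time.

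All 42 arrays correlated best with another array of their own line. Breast luminal markers averaged 8.92 on the log2 scale in SKBR3 and 8.74 in MCF7, against 5.29 to 6.29 in the other lines, with ERBB2 at 12.3 in SKBR3 and the oestrogen-responsive TFF1 at 13.8 in MCF7. Colon markers averaged 4.59 to 5.16, and 3 of 8, VIL1, CDH17 and CDX2, reached 6 in SW620. Lung markers averaged 4.76 to 5.09 and did not separate the lung lines. Fibroblast markers averaged 4.40 to 5.39, leukocyte markers 4.39 to 5.47 and endothelial markers 3.85 to 4.82, and 4 markers of these lists reached 6. The leukocyte marker LCP1 stood at 9.91 in SW620, 8.89 in MCF7 and 7.28 in SKBR3, the fibroblast markers COL1A1 at 6.88 to 7.67 in every line and LUM at 7.61 in SW620, and the endothelial marker CDH5 at 6.72 in SKBR3. The level of TP53 itself, planned as a check of the labels, was not analysed here. The ACTB 3' to 5' probe set difference, a measure of RNA integrity, was 0.74 at 0 h, 0.65 at 12 h and 0.91 at 36 h in SKBR3. It ran from -0.12 to 0.19 in H1299, SW620, A549 and MCF7, and the values of HCT116 are given with PFTα below. The 0 h array of SKBR3 stood apart, with a 75th percentile of 6.43 against 6.68 to 6.98 in the other 41 arrays. The median change of all genes was accordingly 0.18 in SKBR3 and between -0.05 and 0.03 in the other lines, and per-line list values are given relative to it.

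The series asked whether wild-type TP53 limits the transcriptional response to ATO, and the first comparison concerned the response of the 3 non-wild-type lines. At 36 h of ATO, 367 genes were higher and 173 lower than at 0 h in these lines (limma, adjusted p under the threshold of 0.05). GDF15, a stress-induced cytokine, rose by 5.26 ± 0.46 on the log2 scale (SE, 3 lines, adjusted p = 0.0137), which is 38.4-fold. Its other measured probe set rose by 1.51. HMOX1, the haem-degrading enzyme haem oxygenase 1, rose by 5.13 ± 0.76 (adjusted p = 0.0445), and the cystathionine gamma-lyase gene CTH, which makes cysteine, rose by 3.85 ± 0.27 (adjusted p = 0.0101). LY96, a co-receptor of TLR4, rose by 4.95, the pseudogene NMRAL2P by 4.23, CREBRF by 4.11, the protease inhibitor CSTA by 4.02 and PPP1R15A, which restores translation after stress, by 3.74. The largest falls were those of CCDC85B (-2.27), ZNF512B (-2.21), the replicative helicase subunit MCM7 (-2.19), HPDL (-2.13), the phosphatase CTDSP1 (-2.12), B4GAT1 (-2.06), TCF19 (-1.84) and NAT14 (-1.83). A further probe set of CCDC85B moved the other way, by 0.42.

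Of the genes called at 36 h, 14 belonged to the 20 measured members of the ATF4 integrated stress response, the programme that follows amino acid shortage and protein folding stress. They included SESN2 (3.60), DDIT3 (3.51) and CHAC1 (3.31). With the adjustment over all genes 14 of 20 were called, and 18 of 20 were called adjusted over the list alone. The autophagy list had 4 called members of 20, namely MAP1LC3B (2.61), GABARAPL1 (2.55), ATG12 (1.90) and ATG14 (1.52), and 11 adjusted over the list alone. NRF2 targets, the antioxidant genes, had 3 of 20, with HMOX1, the glutathione synthesis gene GCLM (2.04) and ME1 (1.85), and 8 adjusted over the list alone. Of the 8 metallothioneins and zinc exporters, which bind or remove metal ions, MT1F (2.31) and MT1G (1.56) were called, and 8 adjusted over the list alone. The heat shock list had DNAJB4 (2.24) alone among 16 and 2 adjusted over the list alone, the TP53 targets GDF15 and TP53INP1 (2.13) among 23 and 5 adjusted over the list alone, and the DNA replication list MCM7 among 24 by either adjustment. Single members were also called in the immediate early genes (KLF10, 1.38), hypoxia genes (BNIP3L, 1.88), histone genes (H4C8, 2.15) and TGF-beta and YAP targets (SKIL, 0.93), with 1, 3, 1 and 4 adjusted over the list alone. Other measured probe sets of SKIL rose by up to 2.40. Over all genes 540 of 11874 were called, and lists with 1 called member lie near that share. Of lists with no member called over all genes, 5 ER chaperones (2 higher and 3 lower), 4 aryl hydrocarbon receptor targets (2 and 2) and 3 interferon-stimulated genes (2 and 1) were called over the list alone.

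The 36 h calls depended on the lines that entered the fit. The count of 540 became 2 without SW620, 4 without SKBR3, 4 without A549, 5 without HCT116 and 1070 without MCF7, and it was 0 with trend and robust settings. Wild-type lines matter here because both statuses share 1 estimate of the spread. After quantile normalization was applied again, 440 genes were higher and 328 lower. Before 36 h, limma called 0 genes at 6 h, with 1971 at an unadjusted p under 0.05, and 0 at 12 h, with 2492. At 6 h the count was 8 without H1299 and 1 without A549, and at 12 h it was 24 without H1299. At 24 h it called CTH (3.4, adjusted p = 0.00383) and HEY1 (1.83, adjusted p = 0.0441), the latter named after its value was seen. The 24 h count was 24 without H1299, 0 without SW620 or SKBR3, 1 without HCT116 and 613 without MCF7. With array medians subtracted it was 379, 321 higher and 58 lower, and 1 at 6 h, and with quantile normalization applied again it was 1 at 24 h. With trend and robust settings it was 0 at 24 h.

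Averaged over 6 to 36 h, CTH was the single gene called in the non-wild-type lines, at 3.02 ± 0.21 (SE, adjusted p = 0.0163, 8.13-fold), with 2.43 in H1299, 3.49 in SW620 and 3.15 in SKBR3. There were 3163 genes at an unadjusted p under 0.05, against 594 by chance. The largest mean changes that did not pass were HMOX1 (5.06, adjusted p = 0.0731), the inducible chaperone HSPA6 (4.77), GDF15 (4.28), the cystine transporter SLC7A11 (3.92) and LY96 (3.16), and, among lower genes, CTDSP1 (-1.96), ZNF512B (-1.62), the death ligand TNFSF10 (-1.60), MCM7 (-1.59), LRRC45 (-1.59) and CCDC85B (-1.56). GDF15 rose by 1.11 by its other measured probe set. The call of CTH was lost without SW620, SKBR3, HCT116 or MCF7, where 0 genes were called. The count was 228 without H1299, 2 without A549 and 325 with the 24 and 36 h arrays alone. A fit over all arrays with the line as a block, which counts the times of a line as separate arrays, called 3961 genes, 2446 higher and 1515 lower.

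In the non-wild-type lines 14 of 21 gene lists passed camera at the preset correlation. The ATF4 list rose with a median of 1.71 (20 of 20 members higher, adjusted p = 2.39e-10), and 18 members were called adjusted over the list alone against 0 over all genes. Metallothioneins rose with a median of 1.72 (8 of 8 higher, adjusted p = 2.60e-05), NRF2 targets with 1.10 (19 of 20, adjusted p = 3.91e-06), the heat shock list with 0.75 (16 of 16, adjusted p = 6.15e-06), autophagy with 0.59 (20 of 20, adjusted p = 1.38e-06) and proteasome subunits with 0.27 (26 of 27, adjusted p = 4.83e-05). DNA replication and E2F targets fell with a median of -0.63 (23 of 24 lower, adjusted p = 1.09e-07). With an estimated correlation no list passed, with an adjusted p of 0.542 for these lists except the proteasome subunits, at adjusted p = 0.611 with an estimated correlation. Adjusted over the list alone, 8 metallothioneins, 10 NRF2 targets, 11 heat shock genes, 10 autophagy genes, 0 proteasome subunits and 1 replication gene were called. Without SKBR3 the median was 0.48 for the heat shock list and 0.17 for proteasome subunits, and without H1299 it was 0.90 for autophagy.

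The remaining lists of this comparison had larger adjusted p-values in camera. Immediate early genes (0.59, adjusted p = 0.0138), TGF-beta and YAP targets (0.79, adjusted p = 0.0185), hypoxia and glycolysis (0.35, adjusted p = 0.0475) and TP53 targets (0.26, adjusted p = 0.0487) rose, and mitosis (-0.23, adjusted p = 0.00532), homologous recombination and Fanconi repair (-0.30, adjusted p = 0.0135) and ribosome biogenesis (-0.27, adjusted p = 0.0135) fell. With an estimated correlation the adjusted p was 0.542 for TGF-beta and YAP targets and ribosome biogenesis, adjusted p = 0.663 for mitosis and adjusted p = 0.611 for the others. Without SW620 the immediate early genes (0.26, adjusted p = 0.849), TGF-beta and YAP targets (adjusted p = 0.0918), hypoxia genes (adjusted p = 0.268) and TP53 targets (adjusted p = 0.123) were no longer called, and without SKBR3 neither were the TP53 targets (0.14), the Fanconi list or ribosome biogenesis, all at adjusted p = 0.105. The hypoxia call was also lost without H1299 (adjusted p = 0.0795) and that of the TP53 targets without MCF7 (adjusted p = 0.0521). Both calls were lost with the mean of probe sets, the hypoxia list at 0.15 (adjusted p = 0.175) and the TP53 targets at 0.17 (adjusted p = 0.152), and with array medians subtracted (adjusted p = 0.0556 for both). The lists of NF-kB and cytokine genes (median 0.27), BCL2 family (0.14), ER chaperones (-0.08), interferon-stimulated genes (-0.15, with a mean of 0.01), aryl hydrocarbon receptor targets (-0.03), cholesterol synthesis (-0.02, with a mean of 0.02) and canonical histones (-0.21) did not pass. Members were nevertheless called adjusted over these lists alone, namely 5 of 16 ER chaperones (1 higher and 4 lower), 3 interferon-stimulated genes (2 higher and 1 lower), 1 aryl hydrocarbon receptor target (lower), 1 cholesterol gene and 1 histone (both higher). The fry test for changes in either direction gave adjusted p = 0.0374 for ER chaperones, 0.0201 for interferon-stimulated genes, 0.0260 for aryl hydrocarbon receptor targets, 0.0359 for histones and 0.0455 for the BCL2 family. In the lists of this paragraph that passed, the called members over the list alone were 5 TP53 targets, 3 hypoxia genes and 2 immediate early genes, all higher, 8 TGF-beta and YAP targets (7 higher and 1 lower) and 0 in the other 3.

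The response of the wild-type lines was examined in the same way. HMOX1 was higher by 2.42 in A549, 4.39 in HCT116 and 7.02 in MCF7, and GDF15 by 1.18, 1.5 and 3.15. Together with the non-coding RNA LINC00304, these were the only genes at least 2-fold higher in all 6 lines, with means of 4.84 ± 1.67 (SD, n = 6 lines) for HMOX1, 3.11 ± 1.86 for GDF15 and 3.12 ± 1.11 for LINC00304. For GDF15 this holds for the probe set used, as its other measured probe set rose by a mean of 0.72 in the wild-type lines. SLC7A11 changed by -0.07 in A549, 2.24 in HCT116 and 5.81 in MCF7, and HSPA6 by 0.95, 0.43 and 7.39. limma called 0 genes in these lines, with a lowest adjusted p of 0.746 and 655 genes at an unadjusted p under 0.05, against 594 by chance. Among genes of one sign in all 3 lines, the largest mean changes, none past the threshold, were HMOX1 (4.61), LINC00304 (3.31), HSPA6 (2.92), NIBAN1 (2.51), the chemokine CCL26 (1.99) and GDF15 (1.94), and CTDSP1 (-1.35), MCM7 (-1.34), MYBL1 (-1.30), TCF19 (-1.09), GFRA1 (-1.08) and E2F8 (-1.08). A further probe set of MYBL1 moved the other way, by 0.15. The fit with the line as a block called 14 genes, 8 higher and 6 lower.

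The gene lists gave 15 calls in the wild-type lines. The ATF4 list rose with a median of 1.08 (19 of 20 higher, adjusted p = 1.25e-13), with NUPR1 at 1.86 and DDIT3 at 1.77. Metallothioneins rose with 1.06 (8 of 8, adjusted p = 9.79e-07), NRF2 targets with 0.76 (20 of 20, adjusted p = 7.48e-12), hypoxia genes with 0.38 (16 of 20, adjusted p = 5.74e-06), heat shock genes with 0.37 (16 of 16, adjusted p = 3.16e-07), autophagy genes with 0.32 (18 of 20, adjusted p = 1.12e-06), immediate early genes with 0.27 (15 of 20, adjusted p = 0.00157), TP53 targets with 0.13 (16 of 23, adjusted p = 0.0181), BCL2 family genes with 0.11 (16 of 19, adjusted p = 0.0204) and proteasome subunits with 0.09 (25 of 27, adjusted p = 0.00379). DNA replication and E2F targets fell with -0.54 (24 of 24 lower, adjusted p = 8.72e-12), the Fanconi list with -0.44 (13 of 14, adjusted p = 5.51e-05), mitosis with -0.39 (25 of 26, adjusted p = 7.70e-08), histones with -0.29 (10 of 12, adjusted p = 0.0337) and ribosome biogenesis with -0.13 (14 of 16, adjusted p = 0.0337). None passed with an estimated correlation, at an adjusted p = 0.456 with an estimated correlation for all but the proteasome subunits (adjusted p = 0.570). No gene was called over all genes, and adjusted over the list alone 3 NRF2 targets and 5 metallothioneins were called and 0 in the other lists.

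Several of these wild-type list calls rested on MCF7. Without MCF7 the lists of mitosis (-0.07, adjusted p = 0.304), homologous recombination and Fanconi repair (-0.09, adjusted p = 0.172), immediate early genes (0.07, adjusted p = 0.809), the BCL2 family (0.08, adjusted p = 0.126) and histones (-0.05, adjusted p = 0.784) were no longer called. Without A549 the TP53 targets (adjusted p = 0.0586), histones (adjusted p = 0.0663) and ribosome biogenesis (adjusted p = 0.0746) were lost, as was ribosome biogenesis without HCT116 (adjusted p = 0.156) and the histones without SKBR3 (adjusted p = 0.0591). Other lists were still called without MCF7, at smaller medians of 0.40 for the ATF4 list, 0.48 for metallothioneins, 0.28 for NRF2 targets, 0.17 for heat shock genes, 0.11 for hypoxia genes and -0.15 for DNA replication. Without A549 the median was 1.20 for NRF2 targets and 0.52 for immediate early genes, and without HCT116 it was -0.81 for DNA replication, -0.45 for histones, 0.21 for TP53 targets and 0.18 for the BCL2 family. The TGF-beta and YAP targets (0.23), NF-kB and cytokine genes (0.05), interferon-stimulated genes (0.04), ER chaperones (-0.04), aryl hydrocarbon receptor targets (-0.11) and cholesterol synthesis genes (-0.13) did not pass in these lines.

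**Figure D1:**
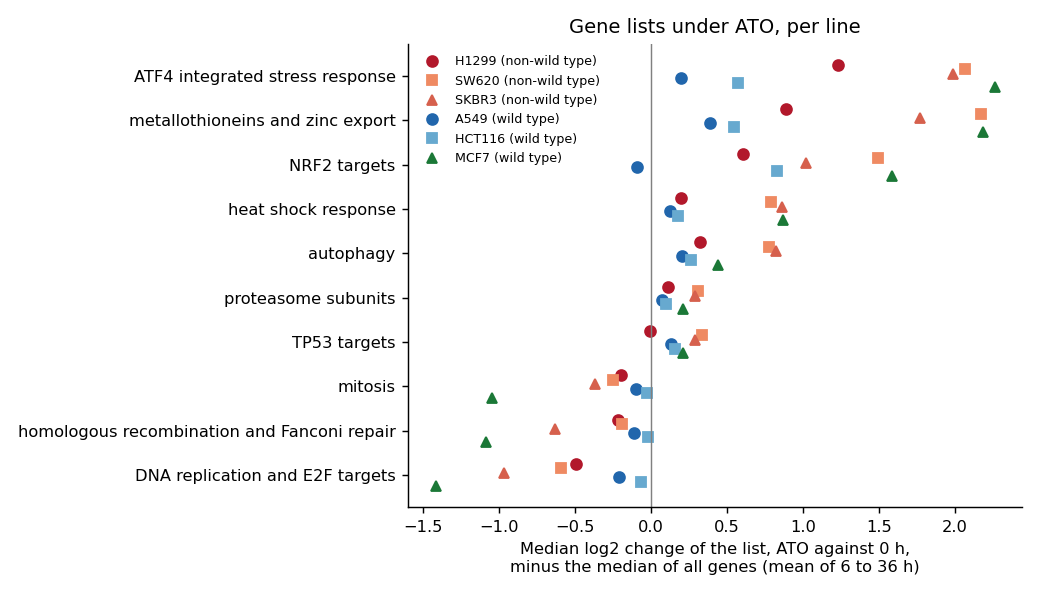
Median log2 change of 10 gene lists in each of the 6 lines under ATO, relative to the median of all genes in that line, as the mean of 6 to 36 h; each point is 1 line. The ATF4 list stood at 2.26 in MCF7, 2.07 in SW620, 1.99 in SKBR3 and 1.23 in H1299, against 0.57 in HCT116 and 0.20 in A549.

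Per line, the ATF4 list relative to all genes stood at 1.23 in H1299, 2.07 in SW620, 1.99 in SKBR3, 0.20 in A549, 0.57 in HCT116 and 2.26 in MCF7. NRF2 targets stood at 0.61, 1.49, 1.02, -0.09, 0.82 and 1.59 in the same order, metallothioneins at 0.89, 2.17, 1.77, 0.39, 0.55 and 2.18, and heat shock genes at 0.20, 0.79, 0.86, 0.13, 0.17 and 0.87. Hypoxia genes stood at 0.15 in A549, 0.13 in HCT116 and 0.88 in MCF7. DNA replication and E2F targets stood at -0.49, -0.60, -0.97, -0.21, -0.07 and -1.42, and mitosis genes at -0.20, -0.25, -0.37, -0.10, -0.03 and -1.05. MCF7, labelled wild type, lay beyond the 3 non-wild-type lines in the 6 lists given for all lines, but not in every list. In autophagy it stood at 0.44, below SW620 (0.78) and SKBR3 (0.82) and above H1299 (0.32). In proteasome subunits it stood at 0.21, below SW620 (0.31) and SKBR3 (0.29) and above H1299 (0.11).

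The number of genes changed at least 2-fold, averaged over the 4 times, was 297 in H1299, 1311 in SW620 and 1956 in SKBR3, against 84.5 in A549, 60.3 in HCT116 and 1234 in MCF7. The non-wild-type lines averaged 1188 ± 836 genes (SD, n = 3) and the wild-type lines 459.5 ± 671, a difference of 728.6 with an exact two-sided permutation p of 0.2, where 0.1 is the smallest possible. Against 0 h the non-wild-type line of each tissue had more such genes, by a ratio of 3.52 in lung, 21.8 in colon and 1.59 in breast. The breast ratio uses the SKBR3 0 h array, and its order turned without that array, with 553 genes in SKBR3 and 619.7 in MCF7 against 6 h (at 36 h 936 and 988) and 91 and 127.7 between successive times. In lung and colon the order stayed, with 180.3 and 68 genes in H1299 and A549 and 672 and 29.7 in SW620 and HCT116 against 6 h. At 36 h the counts were 750, 2398 and 2558 in H1299, SW620 and SKBR3, and 197, 70 and 1846 in A549, HCT116 and MCF7. The SKBR3 count fell to 1737 when its all-gene shift was subtracted. The difference between the statuses was 345 without SKBR3, 1174 without H1299, 1116 without MCF7 and 229 with the 6 h array as the reference.

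**Figure D2:**
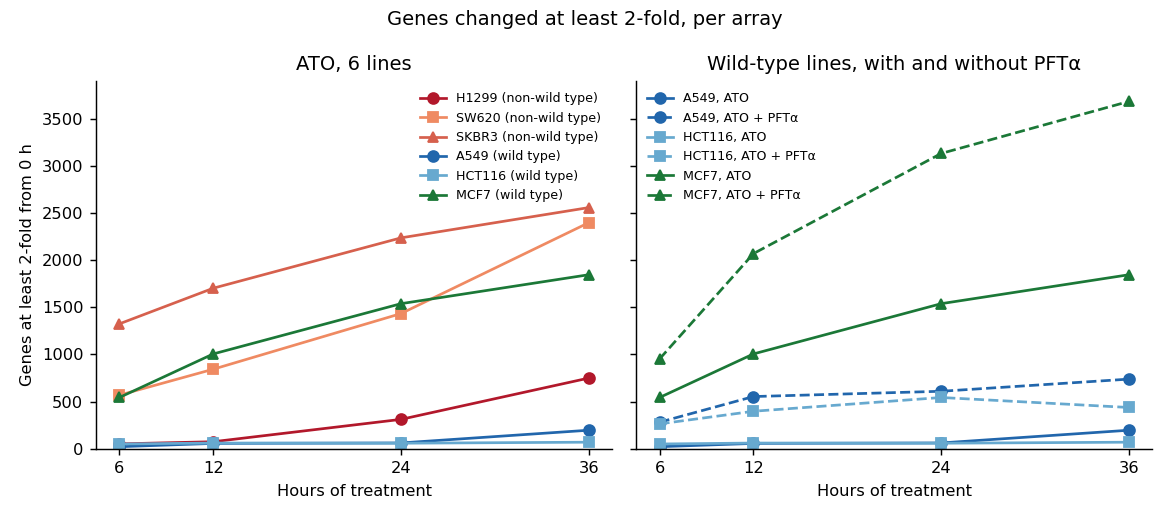
Number of genes at least 2-fold from the 0 h array of the same line, per array, against hours of treatment; the left panel shows ATO in 6 lines and the right panel the 3 wild-type lines with ATO (solid) and with ATO and PFTα (dashed). At 36 h of ATO, MCF7 reached 1846 genes and A549 and HCT116 reached 197 and 70.

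The statuses themselves were compared next. Among genes without overlap between the 3 and 3 lines, the largest differences were higher in the non-wild-type lines for ALDH1L2, a mitochondrial folate enzyme (difference 2.49 ± 0.53, SE), CSTA (2.46), LY96 (2.39), CTH (2.0), LBH (1.77) and the transporter SLC16A4 (1.70). They were lower for ID1, an inhibitor of differentiation factors (-1.26 ± 0.26), CCDC85B (-1.07), DPYSL3 (-1.0), PRRT3-AS1 (-1.0), TMEM163 (-0.98) and B3GNT5 (-0.97). None passed the test of the difference, in which limma called 0 genes with a lowest adjusted p of 0.964 and 409 genes at an unadjusted p under 0.05, against 594 by chance. With the line as a block it called 0 as well, with 1553 at an unadjusted p under 0.05. Without overlap between the 3 and 3 lines were 650 genes higher and 412 lower in the non-wild-type lines, which is 8.94% of genes where chance gives 10%. HMOX1 differed by 0.45 ± 1.13, CDKN1A, the cyclin-dependent kinase inhibitor induced by TP53, by 1.16 ± 0.78 and MDM2, its negative regulator, by -0.16 ± 0.16.

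Among the lists, 3 passed the test of the difference. The ATF4 list rose more in the non-wild-type lines, by a median of 0.67 (19 of 20 members, adjusted p = 0.00141), the autophagy list by 0.32 (19 of 20, adjusted p = 0.00463) and the proteasome subunits by 0.18 (26 of 27, adjusted p = 0.00572). With an estimated correlation each had adjusted p = 0.927 with an estimated correlation, and 0 members were called over all genes or adjusted over the list alone. The ATF4 difference was lost without A549 (0.44, adjusted p = 0.266) and that of the proteasome without SKBR3 (0.07, adjusted p = 0.0832). The ATF4 difference was 0.44 without SKBR3 and 1.28 without MCF7, that of autophagy 0.13 without SKBR3 and 0.53 without H1299, and that of the proteasome 0.29 without H1299. The number of lists called was 6 without H1299, 5 without A549, SW620 or HCT116, 12 without MCF7, and 6 with the mean of probe sets. Of the other lists, metallothioneins (0.63), TGF-beta and YAP targets (0.65), heat shock genes (0.29), NRF2 targets (0.23), TP53 targets (0.09), DNA replication (-0.08), mitosis (0.17), Fanconi genes (0.12), NF-kB genes (0.11), immediate early genes (0.14), cholesterol synthesis (0.17), BCL2 family genes (0.09), histones (0.15), interferon-stimulated genes (-0.05), ER chaperones (-0.08) and ribosome biogenesis (-0.09) did not pass. The hypoxia list (median -0.05, mean 0.07) and the aryl hydrocarbon receptor list (median 0.12, mean -0.00) had a median and mean of opposite sign, and camera gave the Fanconi and BCL2 lists a direction below 0 against medians above it.

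The time course of the lists was described without a test. In the non-wild-type lines the mean of the ATF4 medians was 1.36 ± 0.71 (SD, n = 3) at 6 h and 2.09 ± 0.21 at 36 h, and that of NRF2 targets 0.63 ± 0.42 and 1.27 ± 0.53. The heat shock list was at 0.85 ± 0.47 at 6 h and 0.47 ± 0.48 at 36 h, and DNA replication genes at -0.43 ± 0.17 and -0.83 ± 0.13. In the wild-type lines the ATF4 list was at 0.95 ± 1.02 at 6 h and 1.10 ± 1.0 at 36 h, the heat shock list at 0.51 ± 0.31 and 0.31 ± 0.42, and DNA replication genes at -0.34 ± 0.26 and -0.84 ± 1.17. No single gene passed the test of 36 h against 6 h, which does not use the 0 h arrays. limma called 0 in the non-wild-type lines (2842 at an unadjusted p under 0.05), 0 in the wild-type lines (631) and 0 for the difference (844). In the non-wild-type lines the count was 2 without H1299, 1 without SKBR3 and 10 without MCF7, and for the difference it was 1 without SKBR3.

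**Figure D3:**
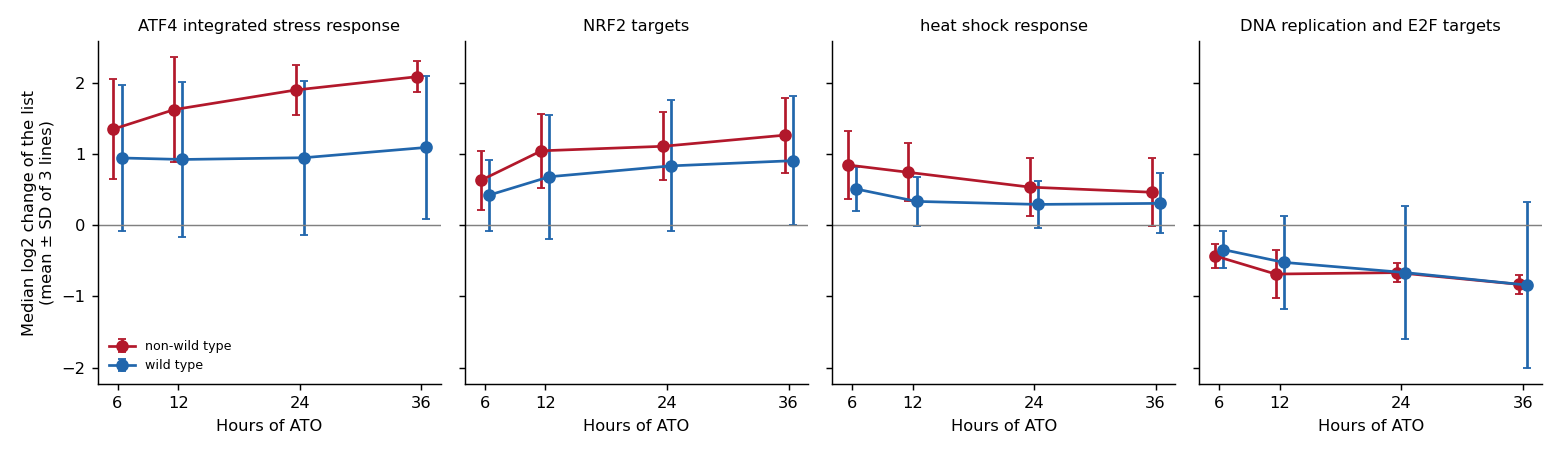
Median log2 change of 4 gene lists against hours of ATO, as the mean of 3 lines per TP53 status with error bars of 1 SD. The ATF4 list of the non-wild-type lines was at 1.36 at 6 h and 2.09 at 36 h, and the heat shock list at 0.85 and 0.47.

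At 36 h the difference between statuses was called for the ATF4 list (0.78, adjusted p = 2.98e-05), autophagy (0.40, adjusted p = 0.00993) and TGF-beta and YAP targets (0.93, adjusted p = 0.0451), each at adjusted p = 0.949 with an estimated correlation. limma called 0 genes for the difference at 6, 12, 24 and 36 h, with 225, 273, 553 and 684 at an unadjusted p under 0.05. In the wild-type lines it called 0 at each of these times, with 732, 701, 609 and 624. Of the 540 genes called at 36 h in the non-wild-type lines, 480 moved the same way in A549, 446 in HCT116 and 518 in MCF7. At least 2-fold in that direction were 40 (7.41%), 22 (4.07%) and 189 (35.0%), respectively.

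The last comparison asked what the TP53 inhibitor PFTα added to ATO in the wild-type lines. Targets of the aryl hydrocarbon receptor, a sensor of aromatic compounds, were higher in all 3. CYP1B1, an enzyme of xenobiotic metabolism, rose by 2.32 ± 0.13 (SE, n = 3, limma adjusted p = 0.0323, 5.01-fold), with 2.56 in A549, 2.06 in HCT116 and 2.35 in MCF7. CYP1A1 was higher by 3.24 ± 0.67 (1.85, 2.39 and 5.48), TIPARP by 1.63 ± 0.16 and the receptor's repressor AHRR by 1.0 ± 0.11, all at adjusted p = 0.243. CYP1A1, CYP1B1 and TIPARP were the only genes at least 2-fold higher in each of the 3 lines, and no gene was that much lower in each. Further large changes of one sign in all 3 lines that did not pass were those of FOS (1.41), MXD1 (1.41), MAFF (1.30), CYP24A1 (-1.28), SLC7A2 (-1.23), SOX2 (-1.17), E2F8 (-1.11), EHF (-1.08) and PRSS23 (-1.01). CDKN1A was 0.68 ± 0.13 higher with the inhibitor (adjusted p = 0.243), and MDM2 differed by 0.16 ± 0.14, with probe sets from -0.16 to 0.38.

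**Figure D4:**
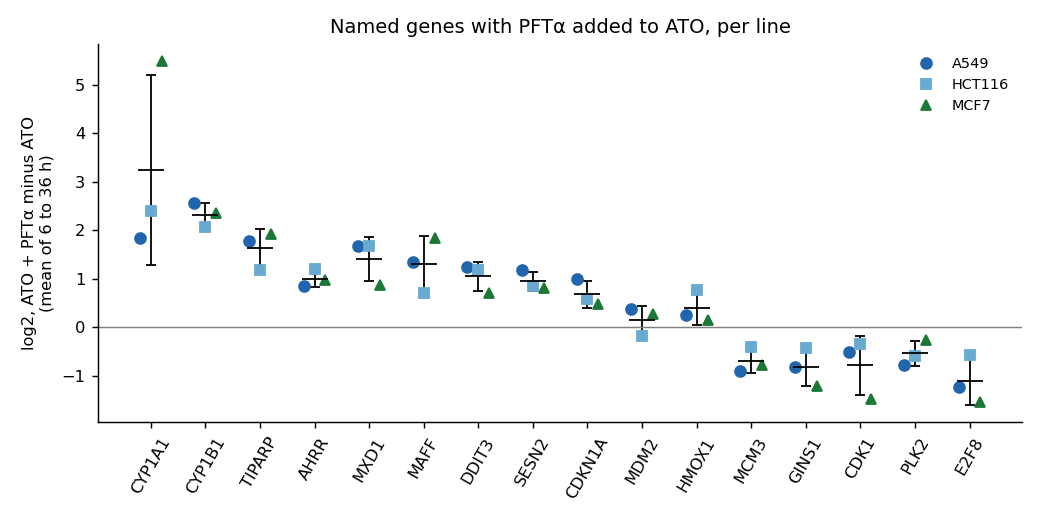
Log2 difference between ATO with PFTα and ATO alone for 16 named genes, as the mean of 6 to 36 h; points are the 3 wild-type lines, horizontal lines the mean and error bars 1 SD. CYP1A1, CYP1B1 and TIPARP lay above 1 in every line.

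limma called CYP1B1 alone for the PFTα effect, with 1754 genes at an unadjusted p under 0.05 against 594 by chance. CYP1B1 was no longer called without HCT116 (2.45, adjusted p = 0.255), and 7 genes were called without MCF7. It was also not called with the mean of probe sets, quantile normalization, trend and robust settings, early or late times alone, or without pairing. A fit over the 12 pairs of line and time called 2978 genes, 1138 higher and 1840 lower. At single times limma called 0 genes, with 1261, 1398, 1566 and 1401 at an unadjusted p under 0.05 from 6 to 36 h. Without MCF7 it called 49 at 6 h and 1 at 36 h.

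For the PFTα effect 13 of 21 lists passed camera. DNA replication and E2F targets fell by a median of -0.49 (22 of 24 lower, adjusted p = 3.19e-11), mitosis by -0.45 (26 of 26, adjusted p = 3.51e-09), the Fanconi list by -0.43 (14 of 14, adjusted p = 6.39e-07) and ribosome biogenesis by -0.37 (16 of 16, adjusted p = 6.39e-07). Aryl hydrocarbon receptor targets rose by 1.0 (7 of 7, adjusted p = 7.40e-07), immediate early genes by 0.56 (19 of 20, adjusted p = 1.15e-09), hypoxia genes by 0.48 (19 of 20, adjusted p = 1.88e-09), metallothioneins by 0.41 (8 of 8, adjusted p = 1.47e-06), the ATF4 list by 0.35 (19 of 20, adjusted p = 1.88e-09), autophagy by 0.20 (14 of 20, adjusted p = 6.32e-05), heat shock genes by 0.20 (13 of 16, adjusted p = 0.00254), ER chaperones by 0.09 (13 of 16, adjusted p = 0.0106) and NRF2 targets by 0.07 (14 of 20, adjusted p = 0.0436). None passed with an estimated correlation, at adjusted p = 0.390 with an estimated correlation for most, 0.447 for mitosis and 0.604 for the heat shock list and NRF2 targets. fry called the aryl hydrocarbon receptor list alone (adjusted p = 0.0289). Over all genes CYP1B1 was the single member called. Adjusted over the list alone, 17 replication genes, 11 ribosome genes, 6 Fanconi genes, 8 ATF4 genes, 5 hypoxia genes, 4 immediate early genes, 4 metallothioneins, 4 aryl hydrocarbon receptor targets, 2 autophagy genes and 1 ER chaperone were called, and in lists that did not pass 1 interferon-stimulated gene (higher) and 1 TGF-beta and YAP target (lower).

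These list values average over 4 times, at which some of them differed, described here without a test as the mean of the 3 lines' medians. The ER chaperones changed sign, with 0.32 ± 0.20 (SD, n = 3) at 6 h, 0.38 ± 0.17 at 12 h, 0.02 ± 0.15 at 24 h and -0.20 ± 0.26 at 36 h. The ATF4 list was at 0.47 ± 0.30 at 6 h and 0.05 ± 0.08 at 36 h. Mitosis genes were at -0.02 ± 0.18 and -0.88 ± 0.54, the Fanconi list at -0.08 ± 0.17 and -0.61 ± 0.30, DNA replication genes at -0.22 ± 0.17 and -0.58 ± 0.26, ribosome biogenesis at -0.11 ± 0.16 and -0.44 ± 0.12, hypoxia genes at 0.08 ± 0.22 and 0.68 ± 0.40 and NRF2 targets at 0.10 ± 0.10 and 0.00 ± 0.34.

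The NRF2 call was lost and its sign turned without HCT116 (-0.04, adjusted p = 0.751), it was lost with the mean of probe sets (0.07, adjusted p = 0.0560), and the heat shock call was lost, with a turned sign, without MCF7 (-0.07, adjusted p = 0.693). The ER chaperone call was lost without HCT116 (0.03, adjusted p = 0.127). Without A549 the median was 0.22 for the ATF4 list, 0.20 for hypoxia genes, 0.27 for metallothioneins and 0.32 for heat shock genes, without HCT116 it was 0.39 for heat shock genes, and without MCF7 it was 0.32 for immediate early genes, 0.25 for NRF2 targets and 0.16 for ER chaperones. TP53 targets stood at a median of 0.01 with PFTα (13 of 23 higher, adjusted p = 0.201) and did not pass. Proteasome subunits (-0.03), NF-kB genes (0.01), cholesterol synthesis (-0.13), interferon-stimulated genes (0.02), histones (0.06) and TGF-beta and YAP targets (-0.11) did not pass either, nor did the BCL2 family, with a median of -0.02 and a mean of 0.06. The ACTB 3' to 5' probe set difference, a measure of RNA integrity, was 1.12 to 1.33 in HCT116 with PFTα and 0.80 to 1.02 without. The list values of this line, and its number of 2-fold genes with PFTα, therefore coincide with a shift in RNA quality. In A549 and MCF7 the ACTB difference moved by 0.04 and 0.08.

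More genes were at least 2-fold from 0 h with PFTα than without it in each wild-type line. Their number was 84.5 with ATO and 546 with both agents in A549 (6.46 times), 60.3 and 411 in HCT116 (6.82 times) and 1234 and 2460 in MCF7 (1.99 times). The mean increase was 679.5 genes, with an exact two-sided sign-flip p of 0.25, the smallest that 3 lines allow, and it was 406 without MCF7. Of the 540 genes called in the non-wild-type lines at 36 h, 106 (19.6%) in A549, 72 (13.3%) in HCT116 and 286 (53.0%) in MCF7 were at least 2-fold changed in that direction when PFTα was present. Moved in that direction at all were 473 with PFTα against 480 without in A549, 463 against 446 in HCT116 and 478 against 518 in MCF7. The number of all genes at least 2-fold from 0 h at 36 h was also higher with PFTα, at 739 against 197, 438 against 70 and 3684 against 1846. Against 0 h, ATO with PFTα gave 0 called genes in the wild-type lines by limma, with 2347 at an unadjusted p under 0.05. The difference between that response and the ATO response of the non-wild-type lines gave 0 as well, with 351.

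Across genes, the PFTα effect and the ATO response of the non-wild-type lines, which share no array, went together. Pearson's r was 0.514 and Spearman's rho 0.484 over 11874 genes, with 65.7% of genes of the same sign, where genes are not independent replicates. Line by line, r was 0.408 in A549, 0.392 in HCT116 and 0.324 in MCF7. For the mean of the lines, r lay between 0.184 and 0.290 when the sign of 1 line's difference was turned. That fall follows from the positive r of each line and is no test of the 0.514.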

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

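Of the tests below, the one of RNA quality behind the PFTα effect, and the reading of the one of a faster SKBR3 response, were chosen only after the result was seen. Between the 3 non-wild-type and the 3 wild-type lines, 3 lists differed in the test of the difference, the ATF4 list (0.67), the proteasome subunits (0.18) and autophagy (0.32), and at 36 h the ATF4 list (0.78), autophagy (0.40) and TGF-beta and YAP targets (0.93); none passed with an estimated correlation. Opposite signs in the statuses were looked for only among the genes named for the difference, and their share of all genes was not counted. Lower in all 3 non-wild-type lines and higher in all 3 wild-type lines were ID1 (difference -1.26), DPYSL3 (-1.0), PRRT3-AS1 (-1.0), TMEM163 (-0.98) and B3GNT5 (-0.97). PLK2 (1.54) went the opposite way. All but PLK2 had been named for a large difference without overlap, so their pattern is no separate support. These 6 genes had an adjusted p of 0.964 in limma. Among 3183 probe sets without a single gene name, which entered no comparison, 1 was at least 2-fold higher under ATO in all 6 lines, with a mean of 2.48 ± 1.37 (SD) and a range of 1.17 to 4.34.

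For the difference between statuses, 10 splits of 3 against 3 lines are too few for a share under 0.05. The real split gave 409 genes at an unadjusted p under 0.05, and the highest of the 9 others, A549, HCT116 and H1299 against MCF7, SW620 and SKBR3, gave 1641. That split, picked after the counts were seen, parts the 3 lines with the fewest 2-fold genes from the 3 with the most, so it points to a structure of the samples that those numbers already show and is no separate test of it. For the tests of a mean change, 4 sign patterns of 3 lines are also too few, and the real pattern was the 1 with the most genes each time. The real value and the highest other were 3163 and 597 in the non-wild-type lines, 655 and 136 in the wild-type lines, 1754 and 544 for PFTα, and 3525 and 706 for the non-wild-type lines at 36 h.

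SKBR3 held 1325 genes at 2-fold already at 6 h, more than any other line. A technical shift of its 0 h array is a candidate explanation. Its 6 h change correlated across genes with the mean of the other lines at r = 0.489, below SW620 (0.629) and MCF7 (0.607), while its change from 6 to 36 h, free of that array, gave 0.571 against 0.474 and 0.453. Quantile normalization left 1021 genes in SKBR3 against 548 in SW620, so the shift may not be the whole of it. Its 936 genes from 6 to 36 h, fewer than the 1434 in SW620, met the bound set beforehand against a faster response, but that bound was wrong because such a count leaves out what changed by 6 h, and as each value for the first 6 h uses the doubted array, a faster response stays open.

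Aryl hydrocarbon receptor targets rose with PFTα, a list called by camera at the preset correlation but not with an estimated one (camera adjusted p = 0.390). RNA quality is argued against by A549, where the ACTB 3' to 5' difference moved by 0.0372 and the list median was 0.849. The median of all genes moved by at most -0.0424, which argues against a shift of whole arrays. With ATO alone the list median was at most 0.226 from 0 h, in MCF7, or 0.274 relative to all genes. The first value met the bound set beforehand against ATO alone. That bound cannot decide, because the PFTα effect is taken against ATO alone and so already leaves it out. Receptor activation by the added compound could account for the list being above 0 in 12 of 12 pairs of line and time. It stays open because no arm with PFTα alone was analysed here. Immediate early genes in MCF7 (1.04) exceeded this list (0.969), so the bound set beforehand was not fully met. Such a rank among lists cannot decide, as a compound may move several lists.

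MCF7, labelled wild type, changed more genes than H1299. An odd 0 h array is argued against by the 988 genes at 2-fold from 6 to 36 h, against 398 in H1299, and noise in dim genes by the 963.5 genes among those reaching 8 on the log2 scale, against 215.75. For a response unlike that of the non-wild-type lines, its correlation with their mean change across genes was r = 0.647, against 0.437 in A549 and 0.488 in HCT116. This met the bound set beforehand against an unlike response. It cannot decide, because A549 and HCT116 changed few genes, which may by itself lower their r. As a hypothesis, a wild-type label may not by itself set the breadth of the response in these lines.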

How the results depend on the processing

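Of the tests in this part, those with the 6 h array as the reference, with lines left out or quantile normalization at single times, and with the genes called at 36 h for the correlation were chosen only after the data were seen. Among counts and main values, 214 settings left the result in place and 64 moved it. Among named genes 3367 stayed, 152 newly passed, 13 were lost and 5 moved, and among medians of called lists 292 stayed, 72 were lost and 2 changed sign. Where no cause is named below, the cause was not tested. With 3 lines per status, single-gene calls lie close to the threshold, and signal over background was not measured per probe set.

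With trend and robust settings, the count was 0 in the non-wild-type lines (main value 1), 0 at 24 h (2), 0 at 36 h (540) and 0 for PFTα (1). The PFTα count was also 0 with the mean of probe sets, 0 with quantile normalization, 0 with 24 and 36 h only and 0 with 6 and 12 h only. In the non-wild-type lines 24 and 36 h only gave 325 genes, and 6 and 12 h only gave 0. With array medians subtracted, 1 gene was called at 6 h and 379 at 24 h in the non-wild-type lines, and quantile normalization gave 1 at 24 h.

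Cell lines pair the arrays. With the line as a replicate block over all arrays the count was 3961 in the non-wild-type lines and 14 in the wild-type lines, and 12 line-by-time pairs as blocks gave 2978 for PFTα. Without pairing, with no replicate block, PFTα gave 0. These blocks count the times of a line as separate arrays, and they changed no other call.

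With 1 line left out, the count ranged from 0 to 228 in the non-wild-type lines, from 0 to 8 at 6 h, 0 to 24 at 12 h, 0 to 613 at 24 h and 2 to 1070 at 36 h. The PFTα count ranged from 0 to 7, at 6 h from 0 to 49 and at 36 h from 0 to 1. The change from 6 to 36 h ranged from 0 to 10 in the non-wild-type lines and from 0 to 1 for the difference. Leaving out MCF7 gave the highest counts at 24 h, 36 h and from 6 to 36 h and for PFTα, and leaving out H1299 those of the mean, 6 h and 12 h. The difference in gene lists ranged from 3 without SKBR3 to 12 without MCF7.

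With an estimated correlation 0 lists were called in the non-wild-type lines (14 at the preset), 0 in the wild-type lines (15), 0 for the difference (3) and 0 for PFTα (13). The fry test of a change on balance in one direction called 0, 0, 0 and 1. The mean of probe sets gave 6 lists for the difference. Under PFTα, with 1 line left out, the NRF2 list ranged from -0.0404 without HCT116 to 0.25 without MCF7, and the heat shock list from -0.0712 without MCF7 to 0.391 without HCT116.

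The correlation of the PFTα effect with the non-wild-type response was 0.514, 0.439 with 24 and 36 h only, and 0.445 to 0.534 with 1 line left out. Over the genes called at 36 h it was 0.798. Those genes were selected by their change in the non-wild-type lines, which may by itself raise r, so 0.798 is no support for the 0.514. The planned correlation over genes called in the mean response was not run, as it had 1 gene. The excess of changed genes in the non-wild-type lines stayed above 0 in each setting run. It ranged from 345 without SKBR3 to 1174 without H1299 with 1 line left out, and was 229 with the 6 h array as the reference and 22.3 between successive times.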

Other observations

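Of the tests in this part, the choice of genes from the fit with the line as a block was made only after its values were seen. That fit over all arrays called 14 genes in the wild-type lines. HMOX1 rose by 4.61 (adjusted p = 0.000125), LINC00304 by 3.31 (adjusted p = 0.000125), and the NADPH-producing malic enzyme ME1 by 0.94 (adjusted p = 0.0213) and GCLM by 1.30 (adjusted p = 0.0241). The selenoprotein genes SELENOT (-0.79, adjusted p = 0.00358) and SELENOH (-0.58, adjusted p = 0.0122) fell, as did the mitochondrially encoded ND6 (-0.97, adjusted p = 0.00154). All 3 were lower in A549, HCT116 and MCF7. The fit counts the times of a line as separate arrays, and the fit with 1 value per line called 0 of these genes.

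Before treatment, NRF2 targets averaged 11.7 on the log2 scale in A549 and 8.78 to 9.28 in the other lines. AKR1B10 stood at 13.7 in A549 against 3.87 to 5.48 elsewhere, and HMOX1 at 10.7. Under ATO the NRF2 list moved by -0.09 in A549 relative to all genes, while HMOX1 was 2.42 higher.

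Whether the level of a list at 0 h went with the number of changed genes was tested over the 6 lines for 3 lists, with exact two-sided permutation over 720 pairings. For NRF2 targets Spearman's rho was -0.6 (permutation p = 0.242, adjusted p = 0.242) and Pearson's r -0.501 (permutation p = 0.272, adjusted p = 0.272), and r was -0.99 without A549 and H1299. For metallothioneins rho was -0.829 (permutation p = 0.0583, adjusted p = 0.175) and r -0.706 (permutation p = 0.108, adjusted p = 0.225), with -0.608 without MCF7 and SKBR3. For TP53 targets rho was -0.6 (permutation p = 0.242, adjusted p = 0.242) and r -0.658 (permutation p = 0.15, adjusted p = 0.225), and r turned to 0.719 without SKBR3 and SW620, so that relation rests on those lines. None passed after adjustment, and 6 lines leave the hypothesis open.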
